A study of Rattus norvegicus with 31 samples.

How the data were processed

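Kidney RNA of rats was measured on 31 two-colour Agilent arrays, 1 array per rat. Per the labels, 4 groups were compared: female and male double-transgenic rats (dTGR) and female and male Sprague-Dawley control rats (SD), all bought at an age of 3 weeks and killed at 7 weeks. Labelled RNA (1 µg of total RNA per sample) of the kidney carried Cy3, and a common reference, RNA pooled from 14 rat cell types, carried Cy5 on every array. No dye swaps were made, so a gene-specific dye effect enters every array alike and cancels in differences between groups. The groups held 8 dTGR females, 8 SD females, 8 dTGR males and 7 SD males; SD male 6 was not analysed here.

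Per the file headers, the arrays were scanned with an extended dynamic range and read with Feature Extraction 9.5.3.1, which gave for each spot a mean intensity and a local background intensity in both dyes. The scanner software also gave processed intensity values that, per the file headers, were detrended over the array surface, background-corrected and dye-normalized within the array by a linear and a lowess step. The authors' deposited series matrix holds 1 log2 value per spot, and how it was normalized is not given in the sources used here. Set against the scanner's own red over green log ratio, its columns correlated at -0.993 to -0.985, so its values are kidney over reference. Its column medians ranged from -0.048 to 0.087, and it served only as an alternative.

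Each array held 45018 spots, of which 1639 were controls. From the mean and local background intensities, the background was corrected by normexp with an offset of 50, the ratios were normalized within each array by loess, and log2 kidney over reference ratios were formed with limma 3.58.1 in R 4.3.3. After the files had been seen, a rule was added because normexp could not be fitted on some arrays: local backgrounds above 10 times the array's median were replaced by that median and the spot was left out, which concerned 52 spots on 5 arrays. Spots that the scanner software called outliers were left out, as were control spots, and saturated spots were kept. Spots of one probe were averaged. A probe was kept if its Cy3 signal was well above background on at least 7 arrays and at least 2 unmarked arrays remained in each group, which left 23577 of 41012 probes. The probe with the highest mean Cy3 signal stood for its gene, and where another kept probe of a named gene gave less than 50% of its change, the values of the other probes are given.

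Probes were named through a table of rat genes of the assembly GRCr8, which was used for names only: 10735 probes matched by accession and 9304 by symbol or synonym, and 20973 kept the name in the file. Altogether 20055 probes carried a gene symbol. Of the 19817 genes and transcripts tested, 10836 had a symbol. Utx was kept under that name as the 1 exception to the table.

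All 4 groups entered 1 linear model per gene (limma, moderated with a trend on the gene's mean log2 ratio, not its signal). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The comparisons were dTGR minus SD within females and within males, the difference between these changes (male minus female), and male minus female within SD and within dTGR. All adjusted p-values of genes and of gene lists come from limma. Where every array of a group lay below background on every probe of the gene, a fold is given as "at least": the brighter group's mean was set against the dimmer group's mean of, per array, the higher of the probe's own Cy3 signal and the lowest signal among probes well above background, after loess and Aquantile, which stays open to dye bias and is a bound under this processing alone. Gene lists for kidney cell types, injury, inflammation, proteolysis, transport, metabolism and blood or neighbouring tissues, 27 in number with 640 symbols, were fixed together with the model, the alternatives and the rule for named genes before the data were examined. The lists held 529 measured symbols. The neutrophil and the adrenal list had 2 measured genes each and were not tested, which left 25 lists.

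Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists of a comparison, and again with a correlation estimated from the data. Beside them, fry tested whether the genes of a list moved, on balance, one way, and in its mixed form whether they moved in either direction; neither form compares a list with other genes. None of the 33 list calls held with the estimated correlation. The genes named were cathepsin L (Ctsl) and Agt in every comparison, the 8 largest rises and the 8 largest falls among called genes with a symbol in each strain comparison, the 6 largest in each direction in each sex comparison, the 10 largest interactions, called genes of the sex chromosome list, and up to 3 called members of each list that was called or held 5 or more called members. Some genes that this rule selects are not reported here. Other genes are named as chosen after their values were seen.

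The arrays lay on 8 slides, and each group filled 2 slides of its own, so slide could enter only as a random block (consensus correlation 0.0592, statmod 1.5.0). Alternatives covered the background correction, the normalization within arrays, Cy3 alone (scaled to the 75th percentile), the filter on dim probes, the rule for probes, the authors' matrix, the groups in the fit, array weights, a replicate block, the slide, a 2-fold threshold and the set test. Array position, slide means, a scaling between arrays, the other Ctsl probe and the removal of doubted arrays were added after seeing the data. Aquantile after loess leaves log ratios as they are and was not run as an alternative.

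The fit was tested on simulated data with 200 changed genes among the 19817 of each comparison. For a change of 0.5 on the log2 scale, 76.1% were recovered in the female comparison, 81.2% in the male, 58.4% in the interaction, 85.2% in the SD sex comparison and 86.6% in the dTGR sex comparison. For a change of 1 the shares were 98.6, 96.1, 89.8, 98.6 and 97.2%, with 10 to 13 false calls per comparison. In each comparison the 1 list that had been shifted was called by camera, and 0 of the unshifted lists were. The simulated genes were drawn independently of each other and without slide effects. The simulation therefore does not test the calls, above all those of lists, where genes are correlated. The number of arrays limits the precision. The labels describe the 8 rats of a condition as biological replicates. The p-values set a difference against the spread between arrays within groups, pooled over the 4 groups and moderated across genes. Because each group filled slides of its own, such a difference can also hold differences between slides.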

Results

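Gene expression was measured in the kidneys of 7-week-old rats of both sexes. Double-transgenic rats carry human transgenes of the renin-angiotensin system and develop high blood pressure with renal damage, and Sprague-Dawley rats were the controls. The title of the series names cathepsin L as a possible sex-specific marker of renal damage, so the strain change within each sex, and its difference between the sexes, are the comparisons the design implies. The data comprised 8 dTGR females, 8 SD females, 8 dTGR males and 7 SD males. Median Cy3 mean signals per array ranged from 74.8 to 93.4, and 19237 to 24355 probes were well above background in Cy3. Within groups, pairs of arrays correlated at medians of 0.968 to 0.978, and 0 pairs held identical values. Over 31 arrays, the first principal component held 30% of the variance and separated all males from all females. The second held 23.6% and separated the strains within males. dTGR females 7 and 8 stood apart on it, at 6.27 and 8.34, within the range of the SD females.

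**Figure D1:**
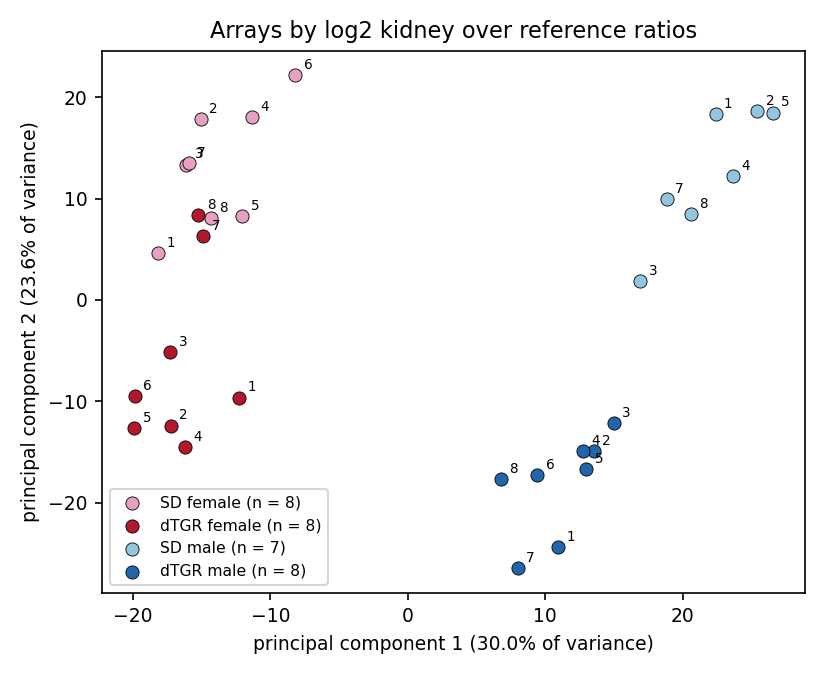
Each point is 1 array, placed by its scores on principal components 1 (30% of the variance) and 2 (23.6%) of the log2 kidney over reference ratios, with its replicate number. Males lie at 6.8 and above on component 1, females at -8.19 and below, and dTGR females 7 and 8 lie among the SD females on component 2.

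The X-linked genes Eif2s3, a translation initiation factor, and Utx, a histone demethylase, were higher on all 16 female arrays than on any of the 15 male arrays. Eif2s3 ranged from -0.59 to -0.19 in females and from -1.40 to -0.80 in males. No Y-linked gene of the sex chromosome list was measured. The probes are rat probes, and whether they bind transcripts of the human transgenes is not known here.

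In females, the largest rises in dTGR were those of Ubd and Havcr1. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, rose 8.65-fold (log2 change 3.11 ± 0.58 SE, 8 against 8 arrays, adjusted p = 0.000462). Havcr1, which encodes kidney injury molecule 1 of damaged proximal tubules, rose 7.51-fold (2.91 ± 0.65, adjusted p = 0.00255) and was above background on 5 of the 8 SD female arrays. All 8 dTGR females lay above the SD female mean for both genes. Of 20 podocyte genes 9 fell, and of 40 proximal tubule genes 4 rose, and neither list call held with an estimated correlation (adjusted p = 0.433 and adjusted p = 0.831).

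Ctsl, the lysosomal cysteine protease cathepsin L, did not pass the test in females. Its log2 ratio was 2.55 ± 0.23 (SD, n = 8) in SD and 2.23 ± 0.25 (n = 8) in dTGR females, a difference of -0.32 ± 0.13 (SE) with an adjusted p of 0.0844. It was lower than the SD mean on 7 of 8 dTGR arrays, and the other Ctsl probe gave -0.34. Agt, the gene of angiotensinogen, fell by 0.56 ± 0.16 on the log2 scale (adjusted p = 0.0139, lower on 8 of 8 arrays).

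Other large rises in females were those of Fam111a, a protease active at replication forks (fitted log2 2.25, 2.003 to 4.477 over the alternatives, adjusted p = 3.42e-05), and Acsm3, a mitochondrial medium-chain acyl-CoA synthetase (3.62-fold, adjusted p = 0.00147). Xdh, the purine-degrading xanthine dehydrogenase, rose 3.15-fold and Igsf1, an immunoglobulin superfamily glycoprotein, by a fitted 1.85 on the log2 scale, 1.38 to 3.778 over the alternatives. Fam111a and Igsf1 were above background on 2 and 1 SD female arrays. RT1-Ba, an MHC class II alpha chain, rose by a fitted 2.46 on the log2 scale, 0.73 to 5.826 over the alternatives, on a probe that was above background on 0 of the 8 SD and on 8 dTGR female arrays, while its other probe gave -0.72. Cyp2b2, a drug-metabolising cytochrome P450, rose 3.73-fold on 4 unmarked arrays per group, and its other probes gave -0.24 to -0.13. The lens crystallin gene Crygd fell 5.26-fold with 0.09 on its other probe, and Dock5, a guanine nucleotide exchange factor for Rac, fell by 1.81 on the log2 scale with -0.44 on its other probe. Ugt2b15, which conjugates steroids, fell by 1.82, Spetex2d by 1.75 and the stearoyl-CoA desaturase Scd2 by 1.58 on the log2 scale, with -0.96 to -0.43 on the other Scd2 probes. The neuropeptide gene Gal fell at least 3.74-fold (adjusted p = 0.0438). Its call ended in 8 of 17 alternatives, among them slide as a random block (adjusted p = 0.089).

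Among gene lists in females, 9 of 20 measured podocyte genes fell and 0 rose (adjusted p = 0.00353, and adjusted p = 0.433 with an estimated correlation). They included the slit diaphragm gene Nphs1 (-0.74 ± 0.21), the intermediate filament gene Nes (-0.62 ± 0.09) and Clic5 (-0.60 ± 0.20, adjusted p = 0.0773 with the slide block), and 10 fell when adjusted over the list alone. The Clic5 call ended in 11 of 17 alternatives. In the list of T, B and NK lymphocyte genes, 5 of 19 fell (adjusted p = 0.00405, and adjusted p = 0.433 with an estimated correlation), and 6 did when adjusted over the list alone. The cytotoxic granule genes Gzmb (-0.59 ± 0.12) and Gzma (-0.41 ± 0.14, adjusted p = 0.0889 with the slide block) and the natural killer receptor gene Klrd1 (-0.50 ± 0.10) were among them, as were Il2rb (-0.32) and Nkg7 (-0.25), named after their values were seen. The Gzma call ended in 12 of 16 alternatives. Of 21 chemokine, cytokine and adhesion genes 5 fell (adjusted p = 0.0423, and adjusted p = 0.831 with an estimated correlation), and 9 fell and 1 rose when adjusted over the list alone. These were the chemokines Cxcl12 (-0.71 ± 0.15) and Cxcl13 (-0.63 ± 0.17), the growth factor Csf1 (-0.45 ± 0.13) and, named after their values were seen, Ccl19 (-0.39) and Il1rn (-0.40).

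Of 40 proximal tubule genes 4 rose in females (adjusted p = 0.00907, and adjusted p = 0.831 with an estimated correlation), or 7 when adjusted over the list alone. Among them were the organic cation and carnitine transporters Slc22a2 (0.69 ± 0.21) and Slc22a5 (0.60 ± 0.21) and, named after its value was seen, Slc17a3 (0.60). With the slide block 1 of the 40 genes rose. The adjusted p of Slc22a2 and Slc22a5 was then 0.0529 and 0.0984, neither below the threshold. The Slc22a5 call ended in 8 of 17 alternatives. In the list of fatty acid oxidation and PPAR alpha, 7 of 27 genes rose and 2 fell (adjusted p = 0.00353, and adjusted p = 0.739 with an estimated correlation), and 11 rose and 3 fell when adjusted over the list alone. The peroxisomal enzyme genes Acox2 (-0.86 ± 0.20) and Acaa1a (-0.60 ± 0.10, other probe 0) fell, and Pex11a of peroxisome division rose (0.58 ± 0.12). The renin-angiotensin list was not called (adjusted p = 0.109), although 5 of its 16 genes fell, among them Nr3c2 (-0.52 ± 0.08, other probe 0.08), the mineralocorticoid receptor gene. In the complement and coagulation list 1 gene rose and 5 of 32 fell (adjusted p = 0.669), with C3 at 0.56 ± 0.19 (adjusted p = 0.0788 with the slide block) and the anticoagulant gene Proc at -0.69 ± 0.12. In the arachidonic acid list 2 of 24 rose and 5 fell (adjusted p = 0.669), with the fatty acid hydroxylase gene Cyp4a1 at 0.72 ± 0.19 and the phospholipase gene Pla2g4a at -0.45 ± 0.10. With the slide block 5 fatty acid oxidation genes rose and 2 fell, 0 complement genes rose and 2 fell, and 2 arachidonic acid genes rose and 2 fell. Of 24 tubular injury genes 4 rose (adjusted p = 0.0844), and 1 of 29 cell cycle genes fell (adjusted p = 0.628). The median, the mean and the test did not share 1 sign in the antigen presentation, loop of Henle, cell cycle, sex chromosome and erythroid lists. By fry, 3 lists moved one way on balance and 15 in either direction.

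Altogether 2781 of 19817 genes passed in females, 922 up and 1859 down, and 91 of them changed at least 2-fold. With slide as a random block the count was 1834 (566 up, 1268 down), with median centring in place of loess 1263 (324 up, 939 down) and with array weights 4986. Array weights also brought Ctsl past the test in females (-0.32, adjusted p = 0.0371), as did leaving out dTGR female 5 (-0.40, adjusted p = 0.0339).

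In males, the largest rises in dTGR were again those of Havcr1 and Ubd. Havcr1 was above background on 0 of the SD male arrays and rose at least 21-fold (fitted log2 change 4.72 ± 0.65, 8 against 7 arrays, adjusted p = 1.83e-06). Ubd rose 22.4-fold (4.49 ± 0.62, adjusted p = 2.39e-06), with all 7 unmarked dTGR arrays above the SD mean. Ctsl rose 2.29-fold, from 0.16 ± 0.31 (SD, n = 7) in SD to 1.36 ± 0.26 (n = 5) in dTGR males (1.198 ± 0.15 SE, adjusted p = 4.82e-07). It was higher on 5 of 5 unmarked dTGR arrays, and the other Ctsl probe gave 0.87. dTGR males 2, 3 and 4, which shared a slide, had no unmarked value on the first probe. On the other probe dTGR male 3 was at 0.57, within the SD male range of 0.17 to 0.71. Of 29 cell cycle genes 25 rose, and the list call did not hold with an estimated correlation (adjusted p = 0.619).

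Agt fell in males by 0.85 ± 0.16 on the log2 scale (adjusted p = 0.000142), on 8 of 8 arrays. Further large rises were those of Acsm3 (4.3-fold) and Adra1d, an alpha-1-adrenergic receptor (3.6-fold). The rise of Acsm3 was enlarged by SD male 5, at a log2 ratio of 2.60. The SD male mean was 5.095 with this array and 5.51 without it. Fgb, the fibrinogen beta chain, rose 4.19-fold (2.07 ± 0.31, adjusted p = 5.39e-06, 8 of 8 arrays), and the protease inhibitor gene A2m rose 3.6-fold on 7 of 8 arrays. The cytokine gene Il24 was above background on 0 SD male arrays and rose by a fitted 1.746 on the log2 scale, 1.577 to 4.435 over the alternatives, on 7 of 8 arrays (adjusted p = 0.000175). Crygd fell 4.22-fold, with -0.14 on its other probe. Igfbp3, which binds insulin-like growth factors, fell 3.86-fold (-1.95 ± 0.23), with -1.57 on its other probe. Myo5c, a class V myosin, fell 3.94-fold and Atp2b3, a plasma membrane calcium pump, 3.06-fold, with -0.16 and -0.33 on their other probes. The mitochondrial ribosomal protein gene Mrpl43 fell 3.84-fold. The cytochrome P450 genes Cyp2d5 and Cyp2c11 fell 3.65-fold (adjusted p = 4.81e-09) and 2.89-fold (adjusted p = 0.00117).

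**Figure D2:**
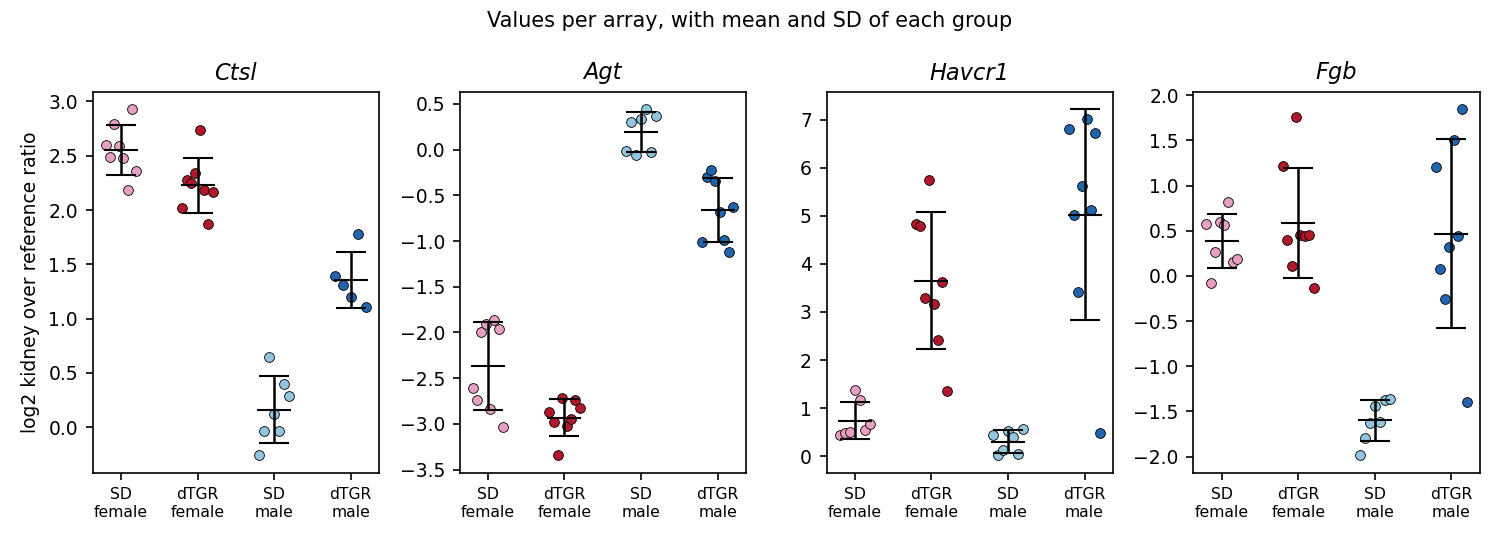
Points are the log2 kidney over reference ratios of Ctsl, Agt, Havcr1 and Fgb on each array by group, with the mean and the SD of the group as bars. Ctsl averages 0.16 in SD males and 1.36 in dTGR males against 2.55 and 2.23 in SD and dTGR females, and 1 dTGR male lies near the SD males in Havcr1 and Fgb.

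The cell cycle list was called in males (adjusted p = 3.48e-10, and adjusted p = 0.619 with an estimated correlation), with 25 of 29 genes risen and 0 fallen, also when adjusted over the list alone. The mitotic kinase genes Cdk1 (1.08 ± 0.23) and Aurkb (0.81 ± 0.16, other probe 0.40) and the replication licensing gene Mcm6 (0.83 ± 0.13) rose on 8 of 8 arrays. By fry the list moved one way with an adjusted p of 0.000245.

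**Figure D3:**
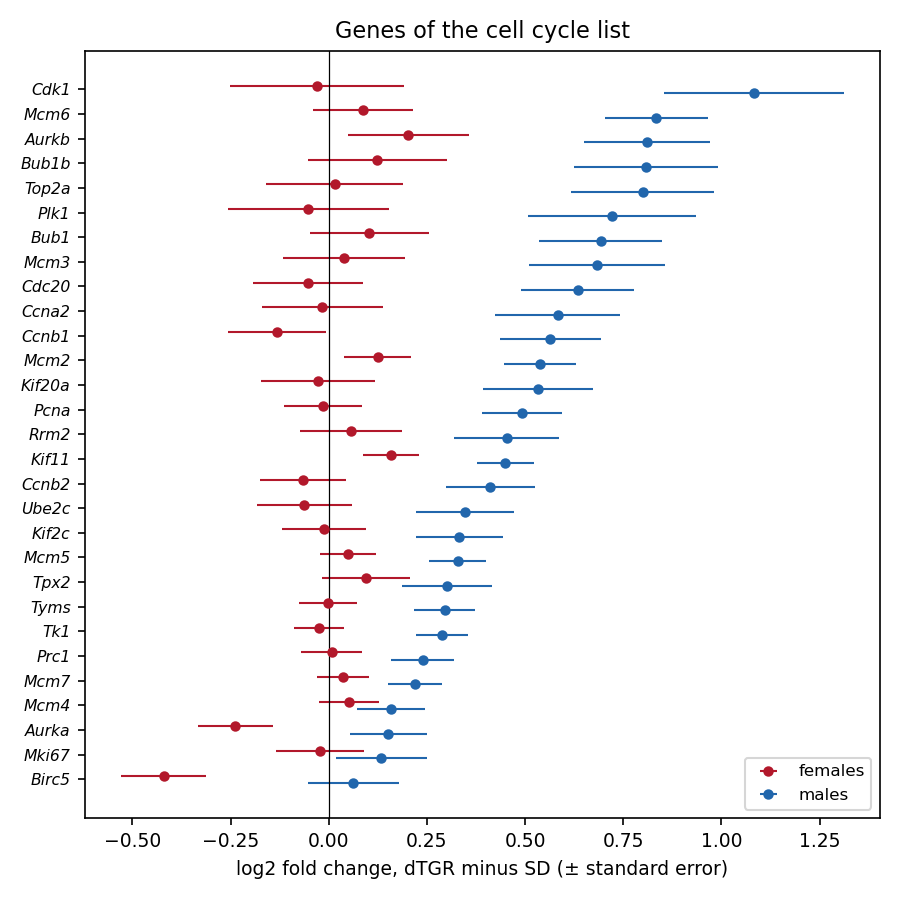
Log2 fold changes (dTGR minus SD, with standard errors) of the 29 measured genes of the cell cycle list in females (n = 8 and 8) and males (n = 8 and 7). In males 25 genes rose past the test, Cdk1 the most at 1.08, and in females 0 rose and Birc5 fell by 0.42.

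Of 24 tubular injury genes 9 rose and 2 fell in males (adjusted p = 0.00679, and adjusted p = 0.7 with an estimated correlation), or 13 and 2 when adjusted over the list alone. Beside Havcr1 the secreted chaperone gene Clu (1.72 ± 0.36) and the osteopontin gene Spp1 (1.57 ± 0.38) rose on 7 of 8 arrays each. Of 35 extracellular matrix genes 9 rose and 1 fell (adjusted p = 0.0456, and adjusted p = 0.785 with an estimated correlation), also when adjusted over the list alone. The metalloproteinase inhibitor gene Timp1 rose (0.85 ± 0.26), the basement membrane gene Nid1 rose (0.68 ± 0.20, other probes 0.16 to 0.17) and Tgfbi fell (-0.75 ± 0.16, other probe -0.02). Of 22 macrophage and myeloid genes 7 rose (adjusted p = 0.00547, and adjusted p = 0.624 with an estimated correlation), 8 when adjusted over the list alone, among them the Fc receptor gene Fcgr2b (0.69 ± 0.18) and the cytokine receptor gene Csf2rb (0.46 ± 0.10). Of 16 antigen presentation genes 5 rose (adjusted p = 0.00621, and adjusted p = 0.619 with an estimated correlation), also when adjusted over the list alone. They were the MHC class II genes RT1-Ba (fitted 1.58 ± 0.10, 0.599 to 4.695 over the alternatives, above background on 0 SD male arrays, other probe -0.38) and RT1-Db1 (0.53 ± 0.14), the immunoproteasome gene Psmb8 (0.47 ± 0.17) and, named after their values were seen, RT1-DMa (0.46) and Tapbp (0.34).

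Some other lysosomal protease genes also rose in males, and whether they moved together with Ctsl was not tested. In the list of cathepsins and cystatins 8 of 17 genes rose, Ctsl among them, and 1 fell (adjusted p = 0.00432, and adjusted p = 0.619 with an estimated correlation), also when adjusted over the list alone. The asparagine endopeptidase gene Lgmn rose by 1.06 ± 0.20 and the dipeptidyl peptidase gene Ctsc by 0.87 ± 0.16, both on 8 of 8 arrays. Of 30 other lysosomal genes 13 rose and 2 fell (adjusted p = 0.00621, and adjusted p = 0.624 with an estimated correlation), or 14 and 2 when adjusted over the list alone. The lysosomal membrane gene Cd63 (0.70 ± 0.13), the hexosaminidase gene Hexa (0.57 ± 0.12) and the beta-galactosidase gene Glb1 (0.56 ± 0.16) rose.

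Among nephron segments, 14 of 40 proximal tubule genes rose and 4 fell in males (adjusted p = 0.0456, and adjusted p = 0.77 with an estimated correlation), also when adjusted over the list alone. The glucose transporter gene Slc2a2 (1.54 ± 0.33, other probe 0.56), the amino acid transporter gene Slc7a7 (1.51 ± 0.38) and the sodium bicarbonate cotransporter gene Slc4a4 (1.35 ± 0.36) rose. Podocyte genes fell in males too, 8 of 20 with 0 risen (adjusted p = 0.0264, and adjusted p = 0.624 with an estimated correlation), also when adjusted over the list alone, with Podxl at -0.81 ± 0.11, Nphs1 at -0.63 ± 0.22 and Ptpro at -0.60 ± 0.14. The complement and coagulation list was not called (10 of 32 up, 3 down, adjusted p = 0.0878), nor were collecting duct (1 of 21 up, 6 down, adjusted p = 0.098) and oxidative stress (7 of 22 up, 2 down, adjusted p = 0.106). Within them Cfi (1.37 ± 0.28), the intercalated cell pump gene Atp6v0a4 (0.81 ± 0.19), the heme oxygenase gene Hmox1 (1.44 ± 0.38) and Cyba, a subunit of NADPH oxidase (0.81 ± 0.16), rose and the anion exchanger gene Slc4a1 (-0.87 ± 0.17, other probe -0.18) fell. Nox4 of the oxidative stress list rose by 0.73 ± 0.28, and its call ended with the slide block (adjusted p = 0.0749). Lists not called but with 5 or more called genes were endothelium (3 up, 6 down), loop of Henle and distal convoluted tubule (3 up, 4 down), renin-angiotensin (2 up, 4 down), fatty acid oxidation (7 up, 4 down), arachidonic acid (3 up, 5 down) and sex hormone receptors and steroid enzymes (3 up, 2 down). Their adjusted p-values were 0.523, 0.669, 0.487, 0.432, 0.752 and 0.609. Members of these lists included the apelin receptor gene Aplnr (0.83 ± 0.13), the magnesium channel gene Trpm6 (-0.55 ± 0.14), Atp6ap2, the prorenin receptor (0.49 ± 0.11), Cyp4a1 (1.44 ± 0.19), the cyclooxygenase gene Ptgs1 (-1.17 ± 0.21) and the glucuronosyltransferase gene Ugt2b7 (1.65 ± 0.14). Medians and means of the chemokine list (-0.06 and 0.02) and of the erythroid list (-0.06 and 0.06) differed in sign. By fry, 12 lists moved one way on balance and 20 in either direction.

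**Figure D4:**
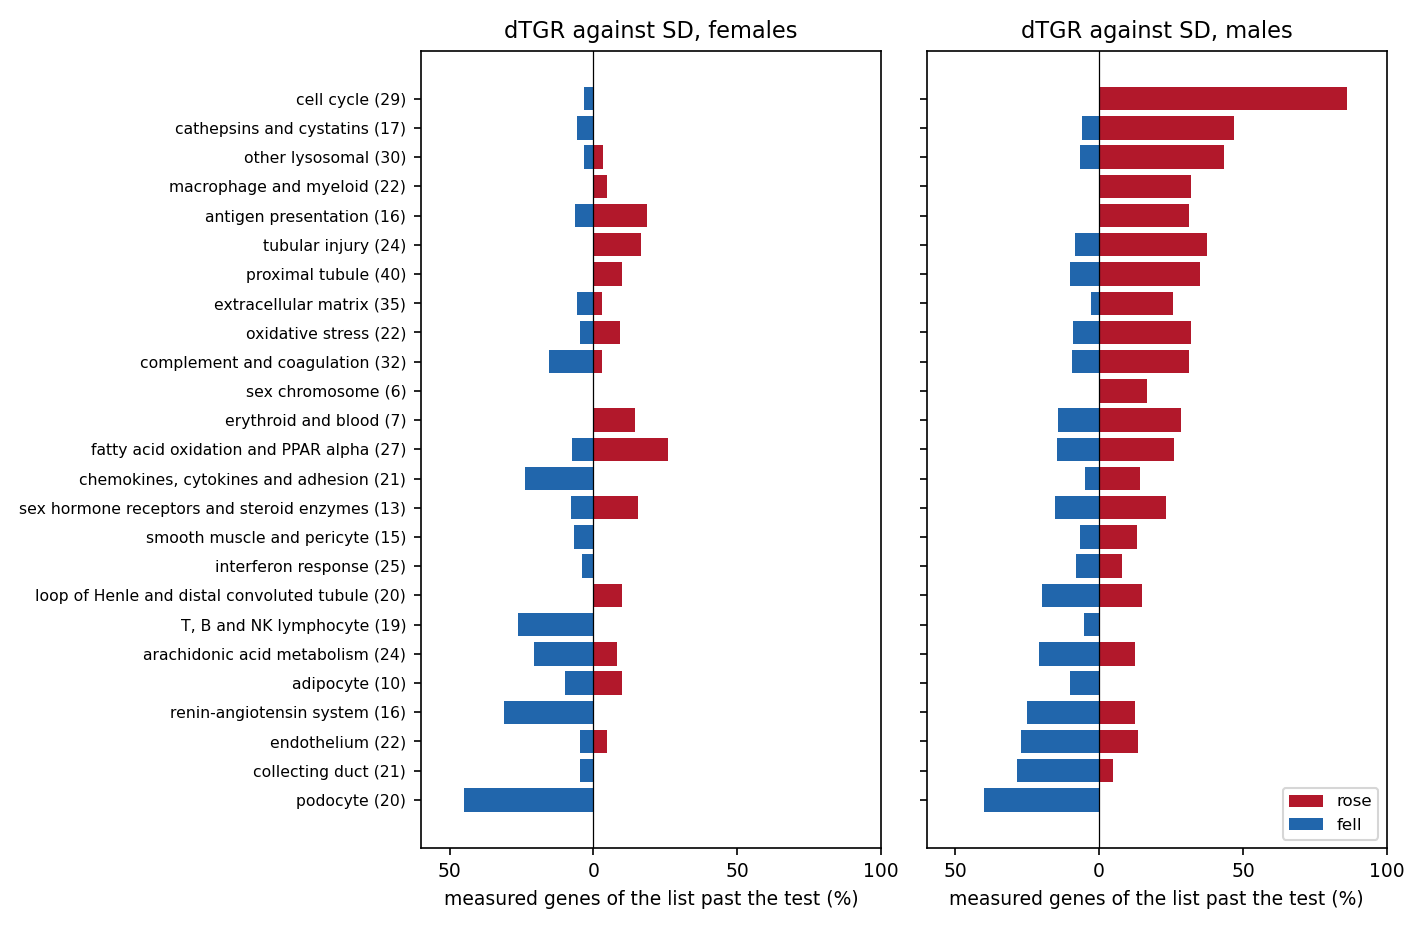
Bars give the percentage of measured genes of each tested list (measured number in brackets) that rose or fell past the test in dTGR against SD, in females and in males. In males 25 of 29 cell cycle genes rose and in females 0 did, while podocyte genes fell in both (9 and 8 of 20).

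In males 6289 genes passed, 3029 up and 3260 down, and 285 changed at least 2-fold. The share of rises was 48.2% and became 68.6% with median centring in place of loess (3141 up, 1438 down).

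The strain changes of the sexes were correlated across genes (Pearson r = 0.628, Spearman rho = 0.591, SD of r over 100 resamplings of the arrays 0.074, 19817 genes, which are not independent replicates). In both sexes 534 genes rose and 1108 fell, against 140.9 and 305.8 for independent lists. Opposite changes were found for 26 genes, against 435.8. The female and male contrasts share no animal.

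**Figure D5:**
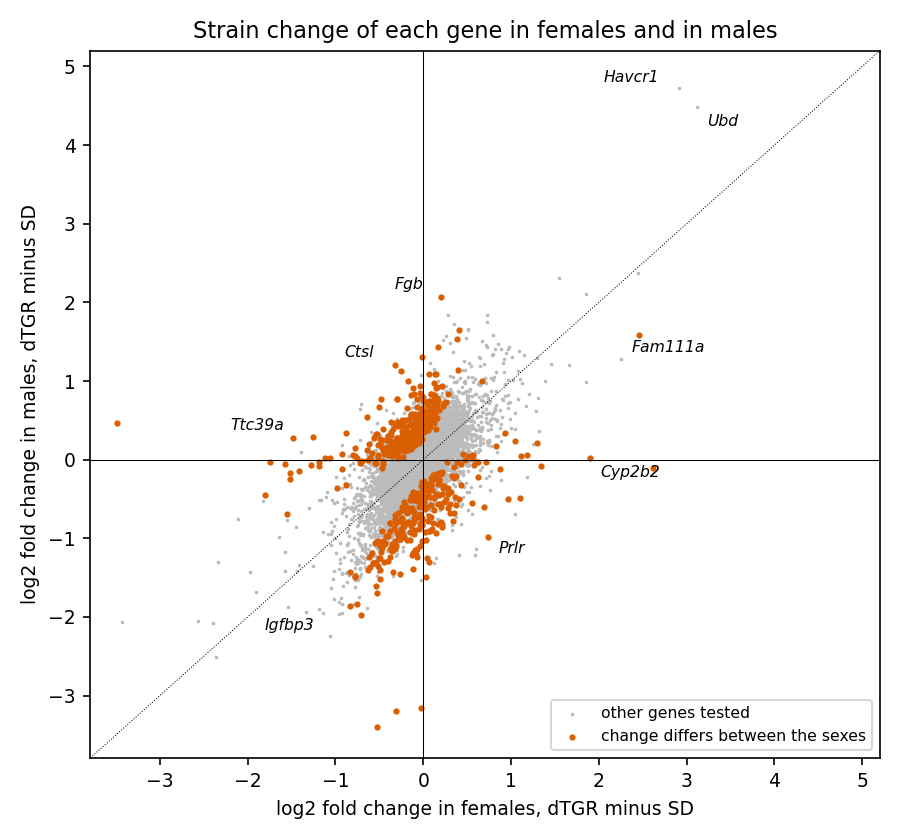
Each point is 1 of 19817 genes, placed by its log2 fold change (dTGR minus SD) in females and in males, with the line of equal change dotted. Orange points are the 560 genes whose change differed between the sexes, among them Ctsl at -0.32 in females and 1.198 in males.

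The difference between the sexes in the strain change was tested directly. Ctsl was among the 10 largest differences: its change was 1.52 ± 0.19 (SE) higher in males than in females on the log2 scale (adjusted p = 2.68e-05, and 0.000173 with the slide block). Fgb differed by 1.87 ± 0.43 (adjusted p = 0.0132), with 2.07 in males and 0.20 in females, and the complement gene C4a by 1.38 ± 0.24 (adjusted p = 0.00164), with 1.12 and -0.25. The prolactin receptor gene Prlr went the other way, at -0.98 in males and 0.74 in females (-1.71 ± 0.26, adjusted p = 0.000172). Of 29 cell cycle genes 4 changed more upward in males, 0 with the slide block, and the list call did not hold with an estimated correlation (adjusted p = 0.591).

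Ttc39a fell by 1.49 on the log2 scale in females and was at 0.27 in males, a difference of 1.76 ± 0.20 (adjusted p = 3.34e-06). Spetex2d and Spetex2f fell by 1.75 and 1.58 in females and were at -0.03 and -0.05 in males, differences of 1.72 ± 0.36 and 1.52 ± 0.29. The stress-response gene Ddit4l rose by 1.34 in females and was at -0.08 in males (difference -1.43 ± 0.35, adjusted p = 0.022, and 0.0564 with the slide block). Slc25a25, a mitochondrial ATP-magnesium/phosphate carrier, was at 0.97 and -0.50 (difference -1.47 ± 0.29, other probe -0.64). Cyp2b2 had the largest difference (-1.88 ± 0.21), on 4 to 6 unmarked arrays per group, and its other probes gave 0.05 to 0.37. Agt differed by -0.29 ± 0.22 without passing (adjusted p = 0.537).

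Of the lists, 10 differed in their change between the sexes. The cell cycle list changed upward in males relative to females (median difference 0.48, adjusted p = 7.32e-13, and adjusted p = 0.591 with an estimated correlation), with 4 of 29 genes past the test over all genes and 24 when adjusted over the list alone. These 4 were Cdk1 (1.11 ± 0.32), Mcm6 (0.74 ± 0.18), the cyclin gene Ccnb1 (0.70 ± 0.18) and, named after its value was seen, Pcna (0.51), and 0 of 29 passed with the slide block. The same direction was found for extracellular matrix (2 of 35, 7 when adjusted over the list alone, adjusted p = 0.00142), complement and coagulation (3 of 32, 6 when adjusted over the list alone, adjusted p = 0.00769) and cathepsins and cystatins (1 of 17, 1 when adjusted over the list alone, adjusted p = 0.00768), each with an adjusted p of 0.591 with an estimated correlation. The 1 called gene of the cathepsin and cystatin list was Ctsl itself. The same direction was also found for macrophage and myeloid (0 of 22, adjusted p = 0.00769), lymphocyte (0 of 19, adjusted p = 0.0232), chemokine (0 of 21, adjusted p = 0.0232), other lysosomal (1 of 30, adjusted p = 0.0232) and antigen presentation genes (0 up and 1 down of 16, adjusted p = 0.0275). For these 5 lists too the adjusted p with an estimated correlation was 0.591. When adjusted over the list alone, 0, 0, 2, 1 and 1 genes of the 5 lists were higher. The adipocyte list went the other way (median -0.38, 0 of 10, 1 when adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.607 with an estimated correlation). Called members were the matrix genes Dcn (0.86 ± 0.19) and Col15a1 (0.84 ± 0.21), the acid glucosidase Gaa (0.44 ± 0.12) and RT1-Ba (fitted -0.88 ± 0.14, -1.131 to -0.132 over 16 alternatives, of which 4 ended the call, other probe 0.33). With the slide block the adjusted p of Col15a1, Gaa, Mcm6, Ccnb1 and Cdk1 rose to 0.0581, 0.0837, 0.0539, 0.0748 and 0.112. The Cdk1 call ended in 11 of 17 alternatives. The median and mean differed in sign in the arachidonic acid, sex hormone and erythroid lists, and in the smooth muscle list both differed in sign from the test. By fry, 3 lists moved one way on balance and 12 in either direction.

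The change differed between the sexes for 560 genes, 306 upward and 254 downward in males relative to females, and 72 differed at least 2-fold. Of these, 365 were called in males alone, 104 in females alone, 62 in both in the same direction, 26 in both in opposite directions and 3 in neither. The count was 221 (108 up, 113 down) with the slide block, 315 (263 up, 52 down) with median centring, 305 without dTGR females 7 and 8, 359 without dTGR male 7 and 32 with slide means. The share of upward differences was 54.6%, and 83.5% with median centring, 41.9% with Cy3 alone (193 up, 268 down) and 68.6% with the authors' matrix.

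Between the sexes in SD kidneys, Dhrs7l1, a short-chain dehydrogenase, was higher in males by a fitted 6.03 ± 0.15 on the log2 scale (7 against 8 arrays, adjusted p = 2.56e-25), and by 4.402 to 9.693 over the alternatives. The organic anion transporter gene Slco1a1 was at least 30.1-fold higher in males and Cyp2c11, the male-specific cytochrome P450 of rat liver, at least 11.9-fold, both above background on 0 SD female arrays. Ctsl was 5.26-fold lower in males (-2.39 ± 0.13, adjusted p = 6.41e-15), on 7 of 7 arrays. Agt was 5.9-fold higher in males (2.56 ± 0.16, adjusted p = 3.19e-14), also on 7 of 7.

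Further genes higher in SD males were the aldo-keto reductase gene Akr1c12l1 (50.9-fold), the transporter gene Slc22a22 (fitted log2 5.45 ± 0.17, 3.888 to 9.029 over the alternatives) and Gc, the vitamin D binding protein (4.04 ± 0.19, 3.527 to 7.021 over the alternatives), each with 7 of 7 male arrays above the female mean. Dhrs7l1, Slc22a22 and Gc were above background on 1 SD female array each, and Akr1b7 and Gsta3l1 on 1 SD male array each. Lower in males were the aldo-keto reductase gene Akr1b7 (fitted log2 -7.30 ± 0.40, -10.104 to -6.363 over the alternatives, on 4 unmarked SD female arrays), the alcohol dehydrogenase genes Adh6 (fitted log2 -5.345, -8.274 to -4.031 over the alternatives, above background on 0 SD male arrays) and Adh1c (11-fold), the glutathione transferase gene Gsta3l1 (-3.25 ± 0.21, -5.603 to -2.338 over the alternatives), the organic anion transporter gene Slc22a7 (7.3-fold) and Dock5 (6.3-fold, log2 -0.55 on its other probe). The X-linked genes Eif2s3 (-0.80 ± 0.08, other probes -0.74 to -0.34), Utx (-0.63 ± 0.06, other probe -0.26) and Ddx3x (-0.37 ± 0.06) were lower in males and Usp9x (0.26 ± 0.08, other probes -0.08 to 0.07) higher.

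No list was called by camera between SD males and females, with 5 at an unadjusted p under 0.05 by camera, and fry found 6 lists moving one way on balance and 21 in either direction. In the proximal tubule list 13 of 40 genes were higher and 5 lower in males (adjusted p = 0.226), among them the cation transporter gene Slc22a2 (3.15 ± 0.21) beside Slco1a1 and Slc22a7. Of 24 injury genes 5 were higher and 1 lower (adjusted p = 0.357), with the transcription factor gene Sox9 at 3.50 ± 0.15 (other probes 0.31 to 0.63) and the growth factor gene Gdf15 at 1.25 ± 0.15. Of 32 complement and coagulation genes 7 were higher and 9 lower (adjusted p = 0.804), with the prothrombin gene F2 at 2.08 ± 0.16, Fgb at -1.98 ± 0.31 and C4a at -0.93 ± 0.17. In the oxidative stress list 5 of 22 were higher and 3 lower (adjusted p = 0.919), and Sod3, the extracellular superoxide dismutase, was at -2.12 ± 0.10. Members of 3 further lists that were not called were Prlr at 2.78 ± 0.18, the estradiol-forming Hsd17b1 at 1.83 ± 0.25 and Hsd17b2 at -1.49 ± 0.25 in a list with 6 of 13 higher and 1 lower (adjusted p = 0.226), Acox2 at -2.04 ± 0.21 with 5 of 27 up and 5 down (adjusted p = 0.95), and Cyp4a8 at 1.52 ± 0.13 with 6 of 24 up and 3 down (adjusted p = 0.234). Podocyte (0 of 20 up, 6 down, adjusted p = 0.0712) and endothelial genes (4 of 22 up, 7 down, adjusted p = 0.316) included Plce1 at -0.92 ± 0.11 and the von Willebrand factor gene Vwf at -0.92 ± 0.16. Lysosomal (2 up, 9 down of 30, adjusted p = 0.234), interferon (1 up, 6 down of 25, adjusted p = 0.233) and lymphocyte genes (2 up, 5 down of 19, adjusted p = 0.919) included Glb1 at -0.81 ± 0.16, Rig1 at -0.60 ± 0.09 (other probe -0.24) and Gzma at -0.92 ± 0.14. The mean, the median or the test differed in sign in the lymphocyte, chemokine, complement, renin-angiotensin, loop of Henle and oxidative stress lists.

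Between SD males and females 6148 genes passed, 2763 higher and 3385 lower in males, and 347 differed at least 2-fold. With median centring in place of loess the split was 759 higher and 5637 lower, a share of 11.9% against 44.9%, and the median of all genes moved to -0.11. Slide means gave 3294 genes.

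Between the sexes in dTGR kidneys, the cell cycle genes were higher in males, 25 of 29 past the test and 0 lower, and the list call did not hold with an estimated correlation (adjusted p = 0.431). Cdk1 was 2.19-fold higher (1.13 ± 0.22, 8 against 8 arrays, adjusted p = 0.000272), the topoisomerase gene Top2a 1.93-fold and the kinase gene Plk1 1.83-fold. Ctsl was 1.83-fold lower in dTGR males than in dTGR females (-0.87 ± 0.14, adjusted p = 3.94e-05), on 5 of 5 unmarked arrays. Agt was 4.82-fold higher in males (2.27 ± 0.16, adjusted p = 4.47e-13), on 8 of 8 arrays.

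The genes with the largest differences in dTGR overlapped those in SD. Akr1c12l1 was 56-fold higher in males, Dhrs7l1 at least 35.8-fold, Slco1a1 at least 29.4-fold, Slc22a22 at least 22.1-fold, Cyp2d5 11.2-fold and Rgn, the calcium-binding regucalcin gene, 10.1-fold. Akr1b7 was at least 86.9-fold lower in males, Adh6 by a fitted log2 -5.77 (-9.107 to -4.387 over the alternatives, above background on 2 dTGR male arrays), Slc22a7 9.07-fold, Adh1c 6.89-fold, Gsta3l1 at least 5.71-fold and the surface antigen gene Ly6i 5.08-fold. The sex differences of the strains were correlated across genes (Pearson r = 0.751, Spearman rho = 0.598), with 1296 genes higher in males in both against 384.1 for independent lists, 1547 lower in both against 448, and 48 opposite against 836.3.

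In dTGR 9 lists were called between the sexes. Beside the cell cycle (adjusted p = 1.82e-12, and adjusted p = 0.431 with an estimated correlation, 27 of 29 when adjusted over the list alone), the extracellular matrix list was higher in males (14 of 35, 17 when adjusted over the list alone, adjusted p = 0.000367, and adjusted p = 0.524 with an estimated correlation). It included the connective tissue growth factor gene Ccn2 (0.73 ± 0.17) and the fibrillin gene Fbn1 (0.62 ± 0.14). Of 24 tubular injury genes 6 were higher, 6 also when adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.524 with an estimated correlation), with Sox9 at 2.51 ± 0.15 (other probes 0.25 to 0.71), Gdf15 at 1.15 ± 0.14 and the adhesion receptor gene Cd44 at 1.06 ± 0.23. Of 21 chemokine, cytokine and adhesion genes 7 were higher, 7 also when adjusted over the list alone (adjusted p = 0.0237, and adjusted p = 0.524 with an estimated correlation), with the monocyte chemoattractant gene Ccl2 at 0.92 ± 0.23. Of 40 proximal tubule genes 9 were higher and 4 lower, or 11 and 4 when adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.558 with an estimated correlation). Lower in males were podocyte genes (0 of 20 up, 6 down, also when adjusted over the list alone, adjusted p = 0.0227, and adjusted p = 0.524 with an estimated correlation), with Plce1 at -0.79 ± 0.11. The collecting duct list was called lower too, stayed called in 8 of 18 alternatives and reversed with the processed signals, at an adjusted p of 0.787 (2 of 21 up, 7 down, or 2 and 8 when adjusted over the list alone, adjusted p = 0.042, and adjusted p = 0.524 with an estimated correlation), with the proton pump gene Atp6v1b1 at -0.95 ± 0.18. Of 6 sex chromosome genes 1 was higher and 3 were lower, also when adjusted over the list alone (adjusted p = 0.0211, and adjusted p = 0.142 with an estimated correlation). These were Usp9x (0.24, other probes -0.09 to 0.33), Eif2s3 (-0.68, other probes -0.56 to -0.30), Utx (-0.52, other probe -0.24) and Ddx3x (-0.19, other probe -0.05). Of 7 erythroid and blood genes 5 were higher and 1 lower, or 6 and 1 when adjusted over the list alone (adjusted p = 0.042, and adjusted p = 0.431 with an estimated correlation), with the haemoglobin genes Hbb at 0.96 ± 0.30 and Hbb-b1 at 0.72 ± 0.17. By fry, 16 lists moved one way on balance and 23 in either direction.

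Among lists not called in dTGR, the complement and coagulation list held F2 at 2.60 ± 0.15 and Vwf at -1.27 ± 0.16 (10 of 32 up, 3 down, adjusted p = 0.0743). The arachidonic acid list (9 of 24 up, 3 down, adjusted p = 0.0693) held Cyp2c11, at least 4.19-fold higher in males, and the oxidative stress list (4 of 22 up, 2 down, adjusted p = 0.674) held Sod3 at -1.41 ± 0.09. In dTGR 5378 genes passed between the sexes, 2755 higher and 2623 lower in males, and 226 differed at least 2-fold. With median centring in place of loess 3463 passed, 845 higher and 2618 lower, a share of 24.4% against 51.2%. Slide means gave 2151 genes.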

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

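The exchanges of whole slides between groups were chosen after the data were seen, and the other tests of this part were not. Genes and array measures whose highest or lowest array stood apart by Dixon's criterion, and genes and lists whose strain change differed between the sexes by the test of the interaction, follow.

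Of 499 groups of arrays tested, 25 held an array that stood apart, which is 5%, and chance gives about 1 in 20 groups, or 5%. On dTGR male 8, 6 genes stood apart from the other dTGR males, among them Ccl21 at a log2 ratio of 3.46, Nox4 at 2.80, Mcm6 at -2.81 and Psmb8 at -2.36. In other dTGR arrays these included Csf2rb at 0.43 (male 1), Utx at -0.67 (male 2), Cyp2b2 at -0.50 (male 4), Tek at 1.91 (female 5) and Cyp4a8 at 3.77 (female 6). In SD males they were Mrpl43 at -0.65 and Spetex2f at 1.82 (male 1), Cxcl13 at 0.52 (male 2), Sod1 at 2.03 and Ttc39a at -1.74 (male 4), Acsm3 at 2.60 and Gzmb at -3.12 (male 5) and Tie1 at 2.79 (male 8). In SD female 2 they were Acaa1a at 2.14 and Dhrs7l1 at 0.66. dTGR male 2 also had the most spots marked as outliers by the scanner software (11.07%), a median Cy5 signal of 163.8 and 24355 probes well above background in Cy3.

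The strain change was higher in males than in females, on the log2 scale, for genes including Fgb (1.87), Ttc39a (1.76), Spetex2d (1.72), Spetex2f (1.52), Ctsl (1.52), C4a (1.38), Dock5 (1.36), Ugt2b7 (1.24), Cdk1 (1.11), Dcn (0.86), Col15a1 (0.84), Aplnr (0.75), Mcm6 (0.74), Sod3 (0.71), Ccnb1 (0.70) and Gaa (0.44). It was lower in males for Cyp2b2 (-1.88), Prlr (-1.71), Slc25a25 (-1.47), Ddit4l (-1.43), Slc22a2 (-1.29), Gc (-1.27), Myo5c (-1.26), Sox9 (-0.99), RT1-Ba (-0.88) and Pex11a (-0.66). With the slide block the calls of Cdk1, Col15a1, Aplnr, Mcm6, Ccnb1, Gaa, Ddit4l, Myo5c and Pex11a ended (adjusted p 0.0522 to 0.112). The median difference was 0.476 in the cell cycle list, 0.253 in macrophage and myeloid, 0.246 in extracellular matrix, 0.241 in chemokines, 0.201 in cathepsins and cystatins, 0.198 in antigen presentation, 0.168 in complement and coagulation, 0.144 in other lysosomal genes and 0.142 in lymphocyte genes. In the adipocyte list it was -0.384.

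The arrays were split in 100 ways into groups of the same sizes, the real split included. Chance differences between single arrays could be excluded for the gene counts within each sex and within each strain. Each group filled slides of its own, and the splits mixed arrays across slides. The splits therefore cannot exclude differences between slides as a source of these counts. In females 1 of 100, the real split, called 2781 genes, and the highest other called 1043. In males 1 of 100 called as many as the real 6289 (highest other 1412), between the sexes in SD 1 of 100 called 6148 (highest other 1792) and in dTGR 1 of 100 called 5378 (highest other 1824). For the interaction 3 of 100 called at least the real 560 genes, and the highest other called 2092, several times as many. These splits shuffled the strain labels within each sex and left the strain changes in the data. Strain changes can thereby turn into interaction calls, so the splits do not exclude chance for this count.

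For the number of called lists, chance could not be excluded. As many lists as the real 5 were called in 36 of 100 splits in females (highest other 13), as many as 9 in 30 in males (highest other 16), as many as 10 in 7 for the interaction (highest other 12) and as many as 9 in 15 between the sexes in dTGR (highest other 13). When slides were exchanged whole between the groups, the exchanges in females called 7 and 9 lists, at least the real 5, with 0 and 188 genes. In males they called 5 and 4 lists and between the sexes in dTGR 8 and 8, under the real 9. Between the sexes in SD, where the labels called 0 lists, they called 6 and 0, with 240 and 0 genes.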

How the results depend on the processing

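The slide means, the array position as a block, the scaling of log ratios between arrays and the removal of dTGR females 7 and 8 or of dTGR male 2 were chosen after the data were seen. Unless a cause is given, the cause was not tested.

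Ctsl kept its direction and its call in males under all 18 alternatives (0.845 to 1.282, adjusted p 1.07e-07 to 0.000915) and in the interaction (1.109 to 1.598, adjusted p 7.78e-06 to 0.0183). The lowest values, 0.845 and 1.109, came from the authors' matrix, where marked spots were not left out. In the other alternatives dTGR males 2 and 4 had no unmarked Ctsl value, so these alternatives rest on largely the same arrays. In females Ctsl ranged from -0.426 to -0.238 (adjusted p 0.0371 to 0.437), and array weights brought it past the test (-0.323, adjusted p = 0.0371). The correlation of the female and male changes ranged from 0.572 to 0.691.

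Median centring gave 1263 genes in females, 315 in the interaction and 3463 between the sexes in dTGR. Array weights gave 4986 in females. The replicate number as a block gave 366 in the interaction. Slide as a random block gave 1834 in females and 221 in the interaction. A 2-fold minimum, which by construction removes smaller changes, left 91 in females, 285 in males, 72 in the interaction, 347 between the sexes in SD and 226 in dTGR. Slide means, with 8 values in place of 31 arrays, gave 800, 3699, 32, 3294 and 2151. Without dTGR females 7 and 8 the interaction had 305, and 11 of the 33 list calls ended: lymphocyte and chemokine in females and in the interaction, extracellular matrix and proximal tubule in males, and chemokine, proximal tubule, collecting duct, podocyte and erythroid between the sexes in dTGR. With an estimated correlation camera called 0 of the 33 lists, against 1 to 2 per comparison at an unadjusted p under 0.05, and fry kept 21 of the 33.

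Leaving out 1 array at a time gave 2055 to 3405 genes in females, 5511 to 6689 in males, 359 (without dTGR male 7) to 807 in the interaction, 5498 to 6337 between the sexes in SD and 4814 to 5761 in dTGR. Ctsl ranged from -0.396 (without dTGR female 5, adjusted p = 0.0339) to -0.27 in females, 1.092 to 1.278 in males and 1.416 to 1.602 in the interaction. Because dTGR males 2, 3 and 4 had no unmarked value on the Ctsl probe used, leaving them out could not change its log2 change.

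With the processed signals, Tie1 reversed its sign to 0.617 between the sexes in SD and 0.528 in dTGR, and Atp6v0a4 to 0.134 in dTGR. None of these passed (adjusted p = 0.157, 0.252 and 0.682). The collecting duct list in dTGR reversed too (adjusted p = 0.787). With Cy3 alone Umod in SD reversed to -0.112 (adjusted p = 0.529). Ppp1r1a in dTGR reversed to -0.538 and passed in that direction (adjusted p = 0.0061).

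Over 4161 values of named genes, without the Ctsl changes given above, 3872 stayed on their side of the threshold, 284 lost the call, 0 gained it and 5 reversed, and over 594 of lists 489, 104, 0 and 1 did. Nearly all of these genes and all of these lists had been chosen because they passed, so few values could gain a call. The list test was not run with slide as a random block, which camera does not take, and scaling of single channels by Aquantile was not run as an alternative. Equal replicate numbers do not pair arrays: 45 pairs with the same number correlated at -0.319 to 0.315 (median -0.075, 6 of 45 above 0.1), and 6 of 31 arrays correlated best with their own number. Genes with Cy3 signals near background are limited by that signal. Folds given as "at least" are bounds under the main processing alone, and some alternatives fell under them. Over the alternatives the log2 change of Havcr1 in males ranged from 3.63 to 6.668. The log2 sex difference of Slco1a1 in SD ranged from 4.03 to 9.091.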

Other observations

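The tests of the proximal tubule list and of sequence differences under probes were chosen after their values were seen. The clock, sex-bias and probe patterns were noticed in these data and tested on them.

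Of 157 genes at least 2-fold higher in SD males than in SD females, 84 were called lower in dTGR males and 4 higher, and of 190 higher in SD females 18 were called lower and 50 higher. SD males enter both comparisons, which by itself gives a negative correlation, but with separate SD males in each the correlations across genes were -0.221 and -0.244, which argues against shared arrays as the whole cause. With separate SD males, genes at a 2-fold sex difference were counted by the sign of their change alone, without a test. So counted, 141 of 190 and 135 of 153 male-biased genes were lower in dTGR males (medians -0.298 and -0.483). Of female-biased genes 119 of 204 and 131 of 227 were higher (medians 0.059 and 0.068). Fewer proximal tubule cells in dTGR males could lower male-biased tubule genes, and the proximal tubule list had a median of 0.198 with a standard error of 0.126 from 200 resamples, too wide to decide. A change in sex-dependent regulation in dTGR males stays open and was not tested.

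Circadian clock genes differed between dTGR and SD females, and in males Nr1d1 was at -0.77 (adjusted p = 0.0106), Per1 at -0.81 (adjusted p = 0.00139), Usp2 at -0.61 (adjusted p = 0.0086) and Wee1 at 0.42 (adjusted p = 0.0021), while Bmal1 (0.06), Cry1 (0.22), Nfil3 (-0.03) and Dbp (-0.16) did not pass. In females Bmal1 rose by 1.18 (adjusted p = 1.67e-05) and Cry1 by 1.30 (adjusted p = 4.09e-07), genes of the clock whose rhythm opposes that of Dbp, and Dbp and Nr1d1 fell by 1.51 and 1.56. A difference in the hour of collection is a candidate explanation: among genes not looked at before, Npas2 minus the median of 9 genes on the side of Dbp was 0.503, although Npas2 was the 1 such gene on its side and Per2, Hlf and Wee1 went against it. Between slides of a female group the clock score differed by up to 0.335, less than the 1.268 between the female groups (0.199 between the male groups). Between the sexes, male minus female, it differed by 0.692 in SD and by -0.377 in dTGR (exact permutation, adjusted p = 0.0114 each). Within SD females it ranged from -1.635 to -0.298. The strain changes of Bmal1, Cry1, Nfil3 and Dbp differed between the sexes (limma, adjusted p 0.00657 to 0.0294). A difference in the hour could thus enter the sex comparisons and the interaction too, which was not tested. The score includes the genes in which the pattern was noticed, which can enlarge the difference between the female groups. It therefore cannot decide whether the slide is the cause. The labels give no hour of collection, and a strain effect on the clock stays open, untested.

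Several large strain changes rested on 1 probe. Genes were taken here by their strain change averaged over the sexes, at least 2-fold, or by their sex difference averaged over the strains. Of 12 such strain genes with another kept probe, 7 had another probe with less than 50% of the change. Of the sex genes 16 of 35 did. Sequence differences between the strains under a probe could do this, and the shares, 58.3% and 45.7%, left it open (Fisher's exact p = 0.517). Dim second probes are a candidate explanation, since the other probe was dimmer in Cy3 by -0.93 on the log2 scale in the discordant genes (6.32 against 7.25, exact permutation p = 0.0126). No biological explanation was tested.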
